A study of Mus musculus with 2 samples.

How the data were processed

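Chromosome contacts were measured by in situ Hi-C, in which DNA is cut and religated inside fixed nuclei so that sequences close together in space are joined and can be counted by sequencing. Per the labels, the cells were mature olfactory sensory neurons sorted by flow cytometry from the olfactory epithelium of adult mice of mixed sex. The mice carried a conditional knockout of Ldb1, a cofactor that bridges transcription factors, driven by a Cre recombinase under the promoter of Omp, a gene of mature olfactory neurons. Each of 2 biological replicates used 1000000 cells, fixation in 1% formaldehyde, digestion with DpnII and biotin tagging. Both libraries belong to 1 group, and no control library was analysed here.

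The submitters combined the contact pairs of both replicates into 1 contact matrix on the mouse build GRCm38, computed a diamond insulation score from it and called boundaries, per the labels' design text and the submitters' processing notes. A diamond insulation score counts the contacts that cross a position, and a boundary is a local minimum where few contacts cross. The boundary caller and its version, its window and its mask of unmappable sequence are not given in the sources used here. The deposited list holds 7610 bins of 5 kb, each with a boundary strength, a score computed by the authors, and a class. In the deposited values every strong boundary had a score of at least 0.500 and every weak one a score under that, and the lowest score was 0.200. The score is the authors' own value for each bin and was used only to describe, rank or split boundaries within this list. Because the list was called on pooled contacts, it carries no replicate error, no library could be left out, and the sequencing depth behind each boundary is unknown. The intervals and permutation tests therefore describe how boundaries were placed along 1 genome and not how the placement varies between animals.

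Coordinates were set against the GRCm38 sequence, with protein-coding genes and transcription start sites (TSSs) from GENCODE release M21 (21755 protein-coding genes on the 20 chromosomes of the list) and functional elements from RefSeq. No boundary lay past the end of its chromosome. Chromosome Y was not analysed here. The 5 kb bins in which more than 50% of the bases were assembly gaps were left out of every random placement. CTCF, the protein that halts loop extrusion by cohesin, was represented by its consensus CCASYAGRKGGC on either strand (12728 matches, 17.6% of them in soft-masked repeats). A match is a sequence, not a binding measurement. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

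A feature counted as being at a boundary when it lay in the bin or within 10 kb of it. Observed shares were compared with 100000 circular shifts of all boundaries within each chromosome, which keep the spacing of boundaries and the clustering of genes. The smallest p these can give is 1e-05. Spacing was compared with 1000 random placements of the same number of bins per chromosome, where the smallest p is 0.001. Strengths, classes and motif strands were permuted within chromosomes 100000 times. Olfactory receptor (OR) clusters were made of protein-coding OR genes at most 200 kb apart, with at least 3 genes. For 13 gene families defined by symbol, the share of TSSs at boundaries was compared with the circular shifts. For 9 lists of marker genes it was compared with 100000 random lists of protein-coding genes, matched in deciles on the number of TSSs within 100 kb. These lists draw genes singly and do not keep the clustering of genes. OR clusters were also compared with 10000 draws of regions outside them, for all boundaries and for strong ones. Each region came from the 200 of the same length nearest in GC and soft-masked share or in TSSs of other genes. Candidate regions began at every 5 kb step and could overlap, so their ranges may be too narrow and their p-values too small. Benjamini-Hochberg adjustment ran over the 13 families and over the 9 lists separately, with a threshold of 0.05. All tests were two-sided. Intervals of shares are exact 95% binomial intervals and intervals of densities exact 95% Poisson intervals. They cover counting error only and treat boundaries or genes as independent, which neighbours are not.

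Most tests, the gene lists and most alternatives were fixed before the data were examined. Tests of the closing section that were chosen after the results were seen are named there. Named genes followed a fixed rule. Ldb1, Lhx2, Ebf1 and Omp were always named. Each list gave the 2 members with the strongest boundary within 10 kb of the TSS, and each marker list also the 2 members farthest from any boundary. The gene with the nearest TSS was named for the 10 strongest boundaries, as were the first and last OR genes of the 3 OR clusters with most genes and of the cluster with most boundaries. The alternatives were the strong class alone, autosomes alone, uniform placement, other windows, other TSS and motif sets, other cluster definitions and another null for gene lists. Moving all boundaries together by 100 to 500 kb, leaving out each chromosome with an OR cluster and random placement with the minimum spacing of the list were added after seeing the data.

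The procedures were tested on simulated data. Lists without an effect were 100 circular shifts of the real list. In these, p was under 0.05 in 3% for TSSs, 8% for the motif, 7% for OR cluster density and 2% for cluster edges. The tests used the same kind of shift, so rates near the threshold were built in. They check the procedure and do not show that the shifts suit the real list. With 15% of boundaries moved to TSS bins, all 100 lists passed and 11.9 of the 12.4 percentage points planted were recovered. Removing 40% of the boundaries in OR clusters was found in 100% of 100 lists. This deficit was larger than the one in the data (ratio 0.795), so the power at the observed size was not tested. Of 200 lists of 25 genes drawn with 4 times the weight for genes at a boundary, 79.5% passed. Of 200 random lists, 2% passed. Both used unadjusted p, and the random lists were drawn singly, as in their null. Most marker lists were smaller and were judged after adjustment, so 79.5% does not give their power.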

Results

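The data describe where chromosome neighbourhoods ended in mature olfactory sensory neurons that lacked Ldb1. These neurons each express 1 of many OR genes, which lie in clusters across the genome. Ldb1 works with the transcription factors Lhx2 and Ebf1, which bind OR enhancers, many of them inside those clusters. There was 1 group of 2 biological replicates, represented by 1 boundary list called on their pooled contacts. Values therefore carry no replicate error, and nothing below compares knockout with normal neurons. A boundary list cannot show whether Ldb1 was lost.

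The list held 7610 boundaries on 20 chromosomes, of which 4022 (52.9%) were strong and 3588 weak. The median strength was 0.538 over the whole list, 0.911 for strong boundaries and 0.301 for weak ones. The strongest boundary of the genome (strength 4.13; chromosome 1, 88305001 to 88310000, GRCm38) overlapped an exon of Trpm8, the cold-sensing channel. The next was at chromosome 11, 3195001 to 3200000 (3.82), in an intron of Drg1 and 1.54 kb from the TSS of Sfi1. The third overlapped an exon of Pdcl (3.23; chromosome 2, 37350001 to 37355000). The nearest TSSs of the other strongest boundaries belonged to Gm527 (strength 3.19), Fstl5 (3.11), Eif1 (3.11), Ppp2r5c (3.06), Trrap (3.05), Efcab14 (3.02) and Jrkl (3.01). Of these 10 boundaries, the one near Gm527 had a CTCF consensus within 10 kb.

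Neighbouring boundaries lay a median of 265 kb apart (interquartile range 185 to 395 kb), against 234 kb under random placement (ratio 1.13, permutation p = 0.001, the smallest possible). No pair was closer than 50 kb, a minimum that can be a setting of the caller, which is not given in the sources used here. With random bins kept at least 50 kb apart, the median was 248 kb (ratio 1.07, permutation p = 0.001). Spacings under 100 kb made up 1.11% of the list, 24.8% of free random placements and 15.9% of those with the minimum. Spacings above 1000 kb made up 2.21% (168), against 5.06% and 3.74%. The coefficient of variation of the spacing was 0.840, against 0.997 and 0.864. Strong boundaries alone varied more in spacing than either placement (1.23 against 1.04, and 0.903 with their own minimum of 100 kb), and they had a median spacing of 390 kb, against 431 kb under random placement (ratio 0.904, permutation p = 0.001). Spearman's rho between neighbours was 0.0036 across 7590 pairs, inside the range of permutations (-0.0022 to 0.0417, permutation p = 0.150), and it was -0.177 among strong boundaries alone (p = 1e-05, the smallest possible). The rho of strength with the distance to the nearest boundary was 0.0295 (permutations -0.0306 to 0.0137, p = 8e-04), and with the distance to the next boundary it was -0.0138 (p = 0.684). For the nearest boundary it was 0.0945 among strong boundaries alone (permutation p = 1e-05) and 0.0398 on autosomes (permutation p = 0.00019). Boundaries are not independent replicates.

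Gene-rich chromosomes tended to carry more boundaries per Mb. Autosomes held 2.999 boundaries per Mb, from 2.54 on chromosome 14 to 3.55 on chromosome 11. Chromosome X held 2.59 per Mb (95% interval 2.35 to 2.85), and 18 of 19 autosomes lay above it. On chromosome X 28.8% of boundaries were strong (exact 95% interval 24.5 to 33.3%). On autosomes 54.3% were, and the lowest autosome had 48.5%. The mice were of mixed sex, and how that bears on chromosome X was not tested. Across the 20 chromosomes, density rose with the number of protein-coding genes per Mb (Pearson's r = 0.686, p = 0.00073; Spearman's rho = 0.710, p = 0.00071; two-sided permutation tests, 1 relation computed). Chromosome 7 ran against this relation. It had the most protein-coding genes per Mb (14.3) but 2.95 boundaries per Mb, under the 2.999 of the autosomes together. Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.729 (permutation p = 0.00062).

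**Figure D1:**
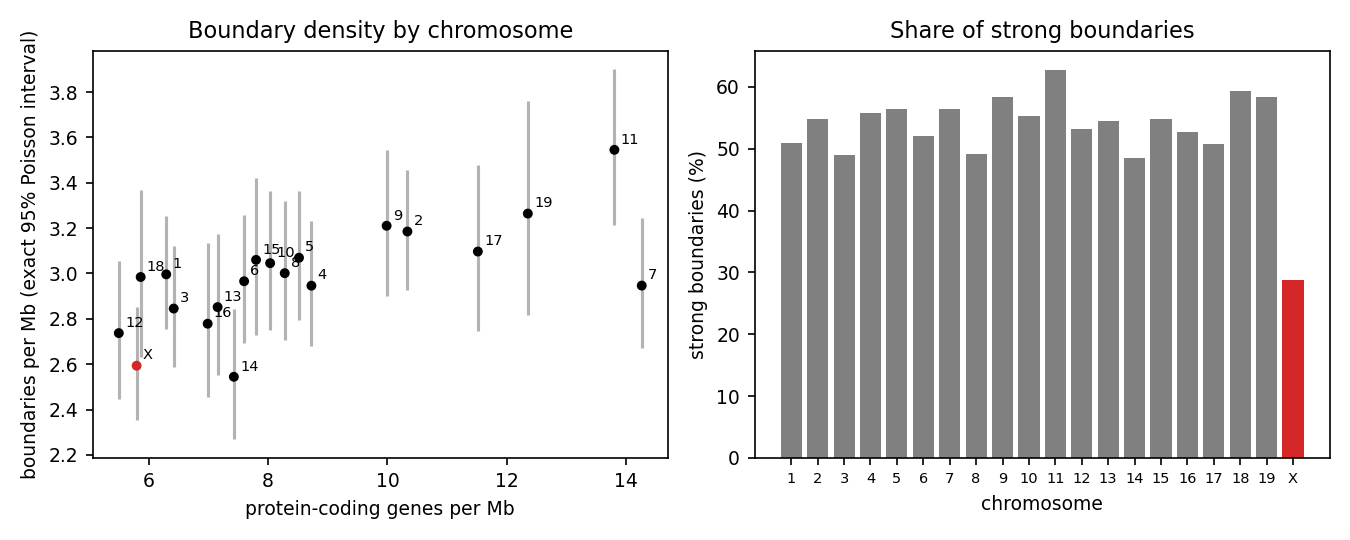
Left, boundaries per Mb (vertical axis, exact 95% Poisson intervals) against protein-coding genes per Mb (horizontal axis) for each chromosome. Right, percentage of boundaries in the strong class by chromosome; chromosome X (red) is at 28.8% and all autosomes are at 48.5% or above.

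Boundaries lay at promoters more often than chance. Of all boundaries, 2369 (31.1%) had a protein-coding TSS within 10 kb, against 17.1% of shifted boundaries (95% range 16.3 to 18.0%; ratio 1.82, permutation p = 1e-05, the smallest possible). TSSs were densest in the boundary bin itself, at 11.02 per 100 bins, and were at 5.30 per 100 bins 300 kb to the left. Exons of protein-coding genes were overlapped by 32.8% of boundaries against 22.5% of shifted ones. Boundaries wholly in introns were rarer than chance (13.4% against 21.4%), and 53.9% lay outside protein-coding genes, against 56.1% (each permutation p = 1e-05). Seen from the genes, 3116 of 21755 protein-coding TSSs (14.3%) were at a boundary, against 7.54% with shifted boundaries.

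The CTCF consensus was also enriched, and its strand was ordered around the boundary. It lay within 10 kb of 1859 boundaries (24.4%), against 11.1% of shifted ones (95% range 10.4 to 11.8%, ratio 2.19, permutation p = 1e-05). Boundaries were not compared with bins of like GC content or TSS density for the consensus. Matches in the boundary bin itself were left out of the count of directions. Of 5782 other matches within 50 kb of a boundary, 3853 (66.6%, exact 95% interval 65.4 to 67.9%) pointed away from it. With permuted strands the share was 50.1% (permutation p = 1e-05). On the left side 1960 of 2886 matches were on the reverse strand, and on the right side 1893 of 2896 were on the forward strand. Reverse matches peaked 5 kb left of the boundary at 4.28 per 100 bins, and forward matches 5 kb right of it at 4.02.

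**Figure D2:**
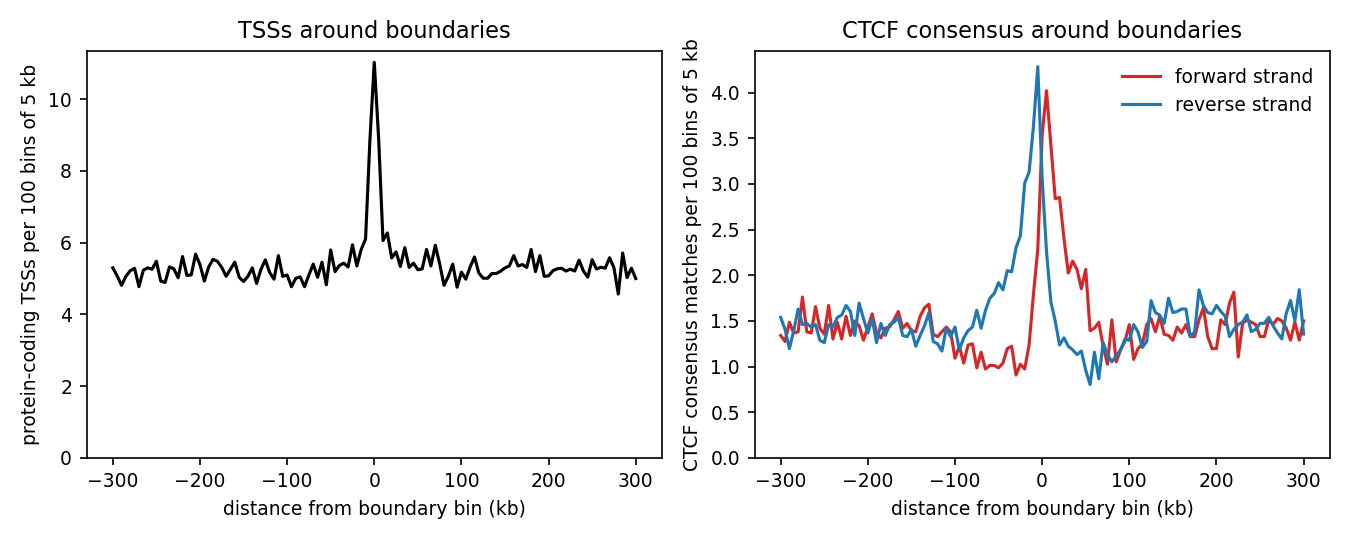
Protein-coding TSSs (left panel) and CTCF consensus matches by strand (right panel) per 100 bins of 5 kb, against the distance from the boundary bin in kb, over all 7610 boundaries. TSSs peak at 11.02 in the boundary bin, reverse-strand matches (blue) peak 5 kb to its left and forward-strand matches (red) 5 kb to its right.

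Strong boundaries had both features more often than weak ones. A TSS was within 10 kb of 37.4% of strong and 24.1% of weak boundaries, a difference of 13.4 percentage points. A CTCF consensus was near 32.0% of strong and 15.9% of weak boundaries, a difference of 16.1 points (each permutation p = 1e-05). Within the bin alone the differences were 4.36 and 4.24 points, and p was unchanged at 1e-05. Boundaries with both features (649) had a median strength of 0.785. Those with the consensus alone (1210) had 0.698, those with a TSS alone (1720) 0.622, and the 4031 with neither (53.0%) had 0.414.

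OR clusters held fewer boundaries than shifted boundaries gave, but not detectably fewer than regions of like GC and repeat content, and boundaries were common at their edges. The 41 clusters covered 28.4 Mb and contained 1066 of 1093 OR genes. They held 70 boundaries, against 88.0 with shifted boundaries (95% range 73 to 104), or 2.46 against 3.10 per Mb (ratio 0.795, permutation p = 0.025). This deficit did not pass without chromosome 2 (ratio 0.877, permutation p = 0.217) or without chromosome 9 (0.814, p = 0.0767), and it passed in the other 14 of 16 omissions. Against regions matched on length, GC and soft-masked share the ratio was 0.942 (permutation p = 0.474), and against regions matched on length and TSSs of other genes it was 0.908 (permutation p = 0.215). Of the 70 boundaries 21 were strong. For these the ratio to shifts was 0.429 (permutation p = 9e-05), to regions of like GC and soft-masked share 0.917 (permutation p = 0.679) and to regions of like TSSs of other genes 0.567 (permutation p = 5e-04). More than 50 kb from an edge lay 49 of the 70 boundaries, 6 of them strong. Matched regions have no such edges, so the ratios to them describe whole clusters and not the interiors alone. Of the 41 clusters, 13 held no boundary of either class. A boundary lay within 50 kb of 52 of the 82 cluster edges (63.4%), against 31.9% with shifted boundaries (95% range 22.0 to 42.7%; ratio 1.99, permutation p = 1e-05). Omitting chromosomes left that ratio between 1.92 and 2.14. Both edges had a boundary within 50 kb in 16 clusters and neither in 5. Such a boundary could lie inside or outside the cluster, and 1 boundary could count for both edges of a short cluster.

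The largest cluster ran from Olfr987 to Olfr1272 on chromosome 2 (85330779 to 90292841) with 217 OR genes. Its 9 boundaries were the most of any cluster, and 1 of them was strong. The nearest boundaries were 45 and 385 kb from its edges. The cluster from Olfr160 to Olfr986 on chromosome 9 (37708964 to 40190134, 93 OR genes) had 5 boundaries, 1 of them strong, and a boundary 35 and 20 kb from its edges. The cluster from Olfr543 to Olfr649 on chromosome 7 (102476579 to 104195985, 91 OR genes) had 5 boundaries, 2 of them strong, and a boundary 10 and 65 kb from its edges. The strongest boundary at any OR promoter (2.62; 102485001 to 102490000) stood at the start of that cluster, in an exon of Olfr544 and 3.32 kb from the TSS of Olfr543.

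**Figure D3:**
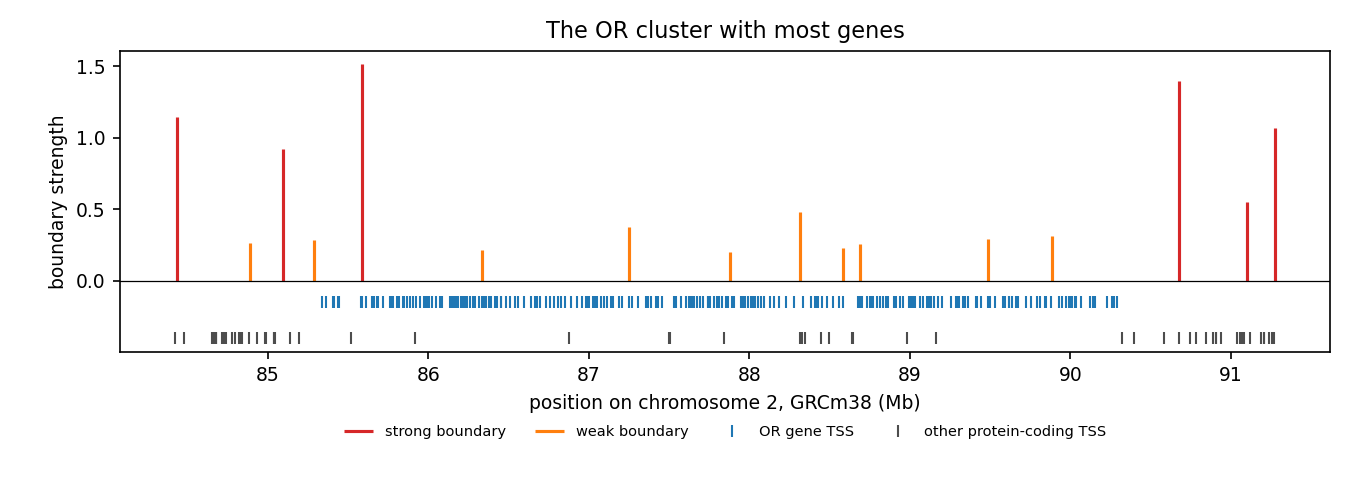
Boundaries (vertical lines, height is the authors' strength score; red strong, orange weak) over the OR cluster from Olfr987 to Olfr1272 and 1000 kb on either side, by position on chromosome 2 (GRCm38, Mb); ticks below mark the TSSs of 217 OR genes (blue) and of 63 other protein-coding genes (grey). Within the cluster 1 of 9 boundaries is strong.

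Among gene families, the promoters of ribosomal proteins stood most often at boundaries. Cytosolic ribosomal protein genes had 28 of 76 TSSs at a boundary (36.8%, exact 95% interval 26.1 to 48.7%; ratio to shifted boundaries 4.87, adjusted permutation p = 6.5e-05), led by Rps23 (boundary strength 2.95) and Rps24 (1.73). Mitochondrial ribosomal protein genes had 19 of 78 (24.4%, ratio 3.17, adjusted permutation p = 6.5e-05), led by Mrps14 (2.18) and Mrps27 (1.63). Proteasome subunit genes had 9 of 39 (23.1%, ratio 3.06, adjusted permutation p = 0.0102), led by Psmd6 (2.74) and Psmc1 (2.59). Solute carrier genes had 45 of 334 (13.5%, ratio 1.77, adjusted permutation p = 0.00065), led by the bile acid transporter gene Slc10a1 (2.22) and Slc17a6 (1.71). The shifts do not allow for the general excess of promoters at boundaries. Of all protein-coding TSSs 14.3% were at a boundary (ratio 1.90), so solute carrier genes showed no excess over other genes. Against random genes of the same local gene density, both ribosomal families still passed (ratios 2.66 and 1.74), while the proteasome (1.64, adjusted permutation p = 0.155) and solute carrier genes (0.920, adjusted permutation p = 0.585) did not.

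The other 9 families did not pass against shifted boundaries. The density-matched lists draw single genes and ignore that members of a family share loci, which the shifts keep, so their p-values are too small for families in tandem clusters. OR genes had 70 of 1093 TSSs at a boundary (6.40%, ratio 0.828, adjusted permutation p = 0.265), and against random genes of the same local density the ratio was 0.495 (adjusted permutation p = 6.5e-05). Among pheromone receptor genes, 9 of 207 vomeronasal type 1 genes were at a boundary, with Vmn1r178 (2.13) and Vmn1r188 (1.78) at the strongest, and 10 of 120 type 2 genes, with Vmn2r80 (2.01) and Vmn2r7 (1.02). Type 1 genes had a ratio of 0.590 to shifts (adjusted permutation p = 0.223) and 0.307 to density-matched genes (adjusted permutation p = 0.00043). Genes with Zfp symbols, mostly zinc finger proteins, had 28 of 365, with a ratio of 1.02 to shifts (adjusted permutation p = 0.999) and 0.539 to density-matched genes (adjusted permutation p = 0.00123). Of the latter, Zfp407 (2.33) and Zfp746 (1.42) had the strongest boundaries. No TSS was at a boundary among 57 clustered protocadherin, 49 keratin and 15 trace amine receptor genes, which gave adjusted permutation p = 0.315, 0.108 and 0.743 against shifts. The first 2 of these families had adjusted permutation p = 0.0167 each against density-matched genes. Histone genes had 11 of 68, with Hist1h1a and Hist1h3a sharing a boundary (1.90), and Hox genes had 3 of 39, with Hoxd10 and Hoxd8 sharing one (1.08).

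No marker list passed adjustment against density-matched genes (0 of 9, and 1 at an unadjusted p under 0.05). That list was cohesin and CTCF genes, which also included Yy1 and Zfp143. It had 6 of 16 at a boundary (37.5%, ratio 2.44, permutation p = 0.0263, adjusted permutation p = 0.237). The strongest boundaries were at the cohesin loader gene Nipbl (0.740) and Esco2 (0.503). Pds5a, Pds5b, Mau2 and Yy1 were at weak ones, and with strong boundaries alone the ratio was 1.21. Smc1a and Stag2 lay farthest away, at 189 and 129 kb. Axon guidance genes had 8 of 30 (ratio 1.79, permutation p = 0.0754, adjusted permutation p = 0.339), including Plxna4 (2.38) and Nrp2 (1.08), with Efnb1 (191 kb) and Sema3f (170 kb) the farthest. Against shifted boundaries, which ignore local gene density, both lists passed (ratios 5.18 and 3.58, adjusted permutation p = 0.0057 each). With the window widened to 25 kb, axon guidance genes also passed against density-matched genes (ratio 1.96, adjusted permutation p = 0.0319).

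Genes of mature olfactory neurons had 5 of 28 TSSs at a boundary (ratio 1.20), among them Gnal, which encodes the olfactory G protein subunit (boundary 1.78, in an exon of Gnal on chromosome 18, 67085001 to 67090000), and Slc17a6, which encodes a glutamate transporter. Ric8b (272 kb) and Kirrel2 (132 kb) were the farthest. Immature neuron genes had 1 of 16, at Stmn2 (0.788), with Gap43 171 kb and Dcx 142 kb from a boundary. Progenitor genes had 2 of 12, at Pcna (0.953) and Top2a (0.298), with Kit and Hes6 290 and 89.0 kb away. Horizontal basal cell genes had 0 of 10 (exact upper bound 30.8%), with Trp63 (281 kb) and Krt15 (174 kb) the farthest. Sustentacular and gland genes had 2 of 13, at Sox10 (0.773) and Sox9 (0.522), with Cyp2a5 and Aqp5 125 and 104 kb away. Immune and vascular genes had 2 of 15, at Cd68 (0.892) and Aif1 (0.249), with Hbb-bs (302 kb) and Cx3cr1 (120 kb) the farthest. These lists stand for cells the sort could have held, whose share a boundary list cannot measure.

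Ldb1 partners and OR choice regulators had 3 of 24 TSSs at a boundary (12.5%, ratio 0.855), with Ehmt1 (0.623) and Ssbp2 (0.451) at the strongest and Lmo3 (387 kb) and Ssbp3 (124 kb) farthest. The TSS of Ldb1 on chromosome 19 was 14.8 kb from a strong boundary (1.43; 46060001 to 46065000, overlapping an exon of Pprc1). The TSS of Ebf1 on chromosome 11 was 12.3 kb from a strong intergenic boundary (1.22; 44600001 to 44605000), and that of Lhx2 on chromosome 2 was 90.7 kb from one (0.626; 38430001 to 38435000). The nearest boundary to Omp on chromosome 7 was weak (0.446; 98195001 to 98200000), overlapped an exon of B3gnt6 and lay 49.5 kb from the TSS.

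**Figure D4:**
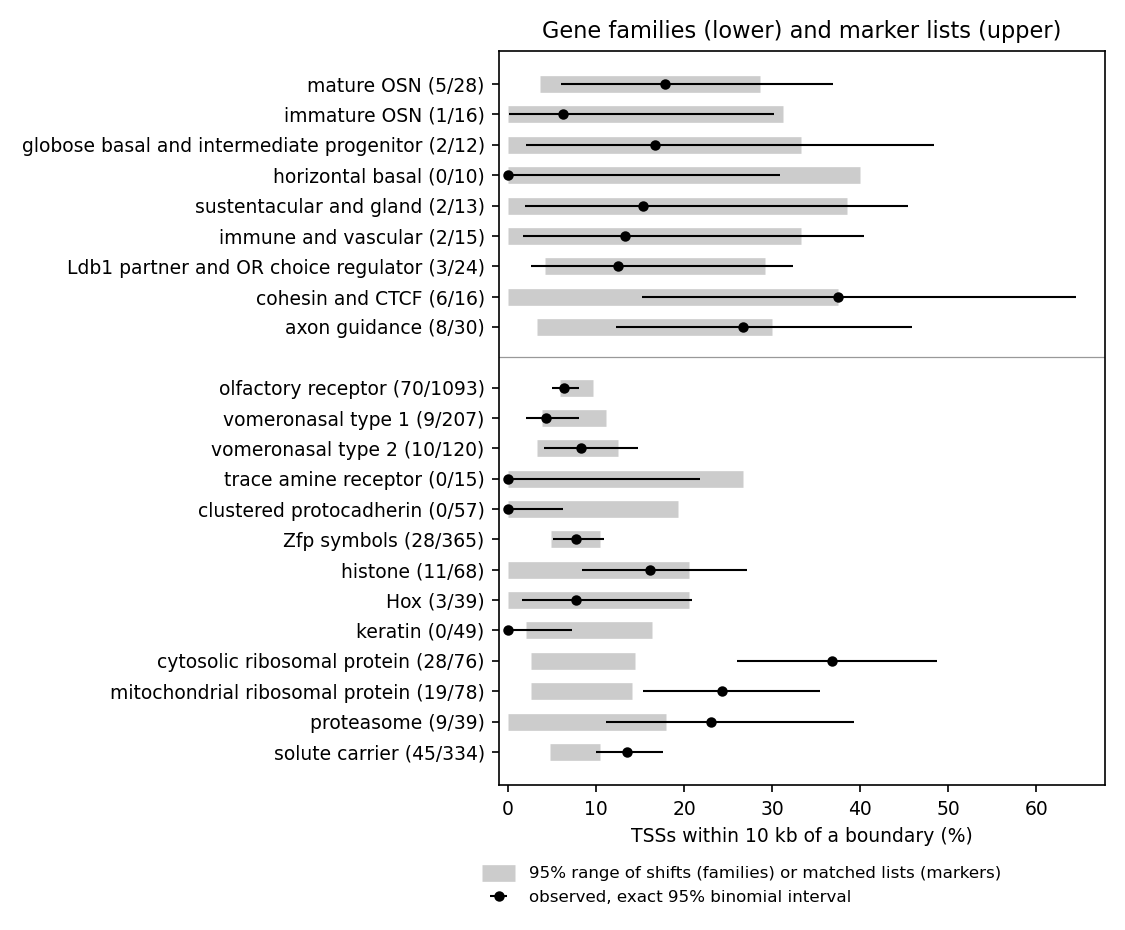
Percentage of TSSs within 10 kb of a boundary (points, with exact 95% binomial intervals; counts in parentheses) for 9 marker lists (top) and 13 gene families (bottom). Grey bars are 95% ranges of density-matched random lists (top) or of shifted boundaries (bottom); cytosolic ribosomal protein genes, at 36.8%, lie farthest above their bar.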

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

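No paired analysis was possible because there was 1 group, and no replicate could be left out because boundaries were called on pooled contacts. Merging boundaries at most 1 bin apart joined none and so tested nothing. Of the 64 other alternatives to the main results set in advance, 56 counted as kept, as did 33 of 35 chosen after seeing the data. For single results this meant the same direction and side of the threshold. For gene families and marker lists it meant a like number of lists passing. The 3 families in place of 4 within the bin only thus counted as kept. TSS enrichment ranged from 1.35 to 2.46, CTCF enrichment from 1.76 to 2.83, orientation from 1.28 to 1.45 and cluster edge enrichment from 1.40 to 2.70, all as ratios to chance and all past the threshold. Density in OR clusters ranged from 0.429 to 0.877 and lost its call without chromosome 2 (0.877, permutation p = 0.217) and chromosome 9 (0.814, p = 0.0767), where fewer clusters were tested. With the strong class alone, the spacing ratio became 0.904 and the rho of neighbouring strengths -0.177. On autosomes that rho was -0.0185 (permutation p = 0.071), against 0.0036 over all chromosomes, where permutations averaged 0.0197. The rho of strength with distance to the next boundary was -0.0138. Density-matched genes as the null gave 7 families in place of 4, with 2 shared: above chance 2 in place of 4, and below chance 5 in place of 0. That null ignores shared loci. It changed the direction for type 2 vomeronasal (0.541), Zfp (0.539) and solute carrier genes (0.920). The adjusted p of solute carrier genes reached at most 0.585 over the alternatives and that of proteasome genes 0.964, where no proteasome TSS lay within the bin itself (ratio 0). Other family ratios that crossed 1 did so without a call. Within the bin only, they were OR genes at 1.18 and Hox genes at 1.62. With strong boundaries they were type 2 vomeronasal at 0.414, Zfp at 0.935 and Hox at 1.72. Within 25 kb they were type 2 vomeronasal at 0.760 and Hox at 1.32. Zfp genes were at 0.9997 on autosomes and Hox genes at 1.03 under uniform placement. Marker lists passing rose from 0 to 2 under uniform placement, 2 under circular shifts and 1 within 25 kb (axon guidance, 1.96, adjusted permutation p = 0.0319; its range was 0.0045 to 1). The first pair of these nulls ignores local gene density. Marker ratios that crossed 1 without a call were progenitor genes with strong boundaries (0.859) and sustentacular genes within the bin (0) and within 25 kb (0.866). Immune and vascular genes were at 1.68 under uniform placement, 1.81 within the bin, 1.28 within 25 kb and 1.71 under circular shifts. Ldb1 partners were at 1.70, 2.11, 1.44 and 1.66 in the same order. Apart from what the construction of an alternative shows, the cause was not tested. The depth of contacts behind the list is unknown, so what it limits could not be assessed.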

Other observations

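The tests of DpnII sites and of OR enhancers, and the descriptions of chromosome X, long stretches and boundary strength in OR clusters, were chosen after the results were seen; the test of strong boundaries in matched regions was added after their deficit against shifts was seen, with its bounds set before it was run. Boundaries inside OR clusters and more than 50 kb from an edge were mostly weak: 6 of 49 (12.2%, exact 95% interval 4.63 to 24.8%) were strong, with a median strength of 0.284. Of the 51 boundaries within 50 kb of an edge, 38 (74.5%, 60.4 to 85.7%) were strong, with a median of 0.755, against 53.0% and 0.539 for the other 7510. Of 11 OR enhancers in the RefSeq annotation, which carry names of Greek islands apart from H, 3 lay within 50 kb of a boundary, inside the 1 to 7 of circular shifts (permutation p = 0.761). These were Sifnos (0.561 kb), Ikaria (11.5 kb) and Fourni (11.6 kb), while H (192 kb), Crete (185 kb) and Lipsi (178 kb) were the farthest. Sifnos, Ikaria, H and Tinos lay outside the OR clusters as defined here. With 11 enhancers, only a large departure would have been seen.

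Of 403 tRNA genes, which are transcribed by RNA polymerase III, 60 (14.9%) lay within 10 kb of a boundary. This was above the 3.23 to 12.7% of circular shifts (mean 7.47%, ratio 1.99, permutation p = 0.00339). It was close to the 14.3% of protein-coding TSSs under the same kind of shift (ratio 1.90). The tRNA genes were not matched on local gene density, so no excess over other genes was shown. The median boundary strength on chromosome X was 0.341, against 0.490 to 0.650 on single autosomes. A TSS lay within 10 kb of 19.6% of its boundaries and 31.8% of autosomal ones, and a CTCF consensus within 10 kb of 10.4% and 25.3%; these differences were not tested. The longest stretch without a boundary was 11975 kb on chromosome X (23840001 to 35815000), with 49 protein-coding genes, 61.7% soft-masked sequence and 14.4% of its bins in assembly gaps. The next were 3860 kb on chromosome 14 (41050001 to 44910000, 80 protein-coding genes), 3730 kb on chromosome 7 (19985001 to 23715000, 94 genes, 56 of them type 1 vomeronasal receptors), 3535 kb on chromosome 2 (174870001 to 178405000, 46 genes, 10 with Zfp symbols) and 3510 kb on chromosome 7 (6950001 to 10460000, 34 genes, 24 of them type 2 vomeronasal receptors). Gaps took 1.34 to 12.7% of the bins of these other 4 stretches. Of the 10 longest stretches, 5 held no gene of the families named here, and whether such families are commoner there was not tested.

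Promoters of cytosolic ribosomal protein genes stood at boundaries more often than other promoters in equally gene-dense places. Against random genes matched on TSSs within 100 kb the ratio was 2.66 (permutation p = 2e-05), and against genes matched also on the GC content of the TSS bin it was 2.40 (p = 1e-05, the smallest possible). These values argue against local gene density, alone or with base composition, as the whole source of the excess in this family. Mitochondrial ribosomal protein genes were not matched on GC content. A candidate explanation is that strongly and constantly transcribed promoters tend to mark boundaries, but no biological explanation was tested, since no expression values were used here and the design has 1 group.

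The excess of TSSs at boundaries was likewise weighed against sequence and method. Among bins with like numbers of DpnII sites, boundaries had a TSS 1.86 times as often as other bins (95% interval from resampled chromosomes 1.77 to 1.95), and among bins of like GC content 1.61 times as often (1.54 to 1.69). Among the 4680 boundaries without a CTCF consensus within 25 kb, 27.9% had a TSS, against 16.8% of shifted ones (ratio 1.66, permutation p = 1e-05). None of these 3 accounts for the whole excess, though sites of CTCF that differ from the consensus may remain among the 4680 boundaries. The submitters' mask of unmappable bins stays open and was not tested, as does any biological explanation.

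The low number of boundaries in OR clusters may follow from the kind of sequence they hold, as they had 38.7% GC, 46.8% soft-masked sequence and 4.12 TSSs of other genes per Mb, against 41.8%, 34.3% and 8.07 over the genome. Regions matched on length and TSSs of other genes held 37.0 strong boundaries on average (95% range 28 to 46). The clusters held 21 (ratio 0.567, permutation p = 5e-04), which weighs against few promoters as the whole source of the strong-class deficit. Candidate regions could overlap, so this range may be too narrow and this p too small. Over both classes the matched regions held 77.1 (66 to 88, ratio 0.908, permutation p = 0.215). Regions matched on length, GC and soft-masked share held 74.3 boundaries of both classes (63 to 85, ratio 0.942, permutation p = 0.474). They held 22.9 strong ones (16 to 30, ratio 0.917, permutation p = 0.679). Base composition and repeats thus stay open for both. The cluster counts include boundaries near cluster edges, which matched regions lack, so cluster interiors were not compared alone. If 1 chromosome were the source, the ratio over both classes was to reach 0.9 with that chromosome left out. The highest ratio was 0.877, without chromosome 2, which is under that bound. Its permutation p of 0.217 compares it with shifts and not with 0.9. How far 0.877 lies from 0.9 was not tested, so a part played by chromosome 2 stays open. An effect of losing Ldb1 could not be tested without control neurons.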
